A study of Ovis aries with 10 samples.

How the data were processed

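RNA from adrenal glands of sheep fetuses was sequenced in 10 libraries with a strand-specific kit, per the labels' protocols. The submitters' processing notes name fastp 0.19.4, Salmon 0.9.1, DESeq2 without a version and the genome build Oar_v3.1, and give none of them a role. The authors deposited a table of estimated counts per gene, which need not be whole numbers, and a table of TPM with the same 20781 gene IDs. The IDs have the form ENSBTAG, which Ensembl uses for cattle genes, although the samples are from sheep. How they relate to the build named in the notes was not determined. The authors give no symbols for these IDs. The gene table used as reference, that of the sheep assembly ARS-UI_Ramb_v3.0, held 0 of them. Names were never matched by value. Coordinates are not given here because that assembly is not the build named in the notes.

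The authors also deposited a table of differential expression with 19316 rows, 13881 with a gene symbol and 5435 with a transcript ID. Of its 13879 distinct symbols 12991 are in the reference gene table. It holds means of groups A and B, a log2 column, a standard error, a score, p-values and adjusted p-values, per the file headers. The means were read as TPM and the score as a Wald score, which the headers do not state. The log2 column equals the log2 ratio of the mean TPM plus 1 in every row. The log2 fold changes printed from this table are instead the authors' score times its standard error, which is the fold change of the authors' count model. Among rows with a mean of at least 1 TPM the median was 0.011 on the model scale and -0.10 on the TPM scale, so values on the TPM scale sit lower. In 80 rows the authors' p-value and adjusted p-value are set to 1, and these were treated as having no p. The groups appear only as A and B. B was taken as endotoxin from the series title, which says that cortisol-producing enzymes were high following inflammation, and if that were wrong every direction from this table would turn. Counts of changes of at least 4, 8 and 16-fold were compared with the labelled TPM table: 40, 16 and 9 were higher and 8, 3 and 1 lower with endotoxin there, and 34, 19 and 12 were higher and 7, 3 and 1 lower in B. A further table of the authors gives KEGG categories with numbers of changed genes and p-values, per the file headers, with no adjustment for the number of categories. It has 98 rows for 95 distinct categories, over which the p-values were adjusted here.

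The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, filterByExpr by group) in R 4.3.3. The model held group for the main comparison, group and sex for sex, and their interaction for the difference in effect. All 10 libraries entered each fit. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. The labels do not state that each library is from a separate fetus of a separate ewe, so p-values of these fits measure the spread between these samples. Totals per library were 12494386 to 18324516 estimated counts, and TMM factors lay between 0.949 and 1.04.

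The steps were tested on counts simulated from the real means, library sizes and edgeR's dispersions for the comparison of endotoxin and control. Of 14869 genes 200 were changed, all above a minimum mean count, so recovery of low-count genes was not measured. edgeR recovered 48% of genes changed 2-fold and 96% of those changed 4-fold, with 1 false call. DESeq2 1.42.0 recovered 72% and 99%, with 42 false calls, and with no gene changed it called 12 genes where edgeR called 0. The list test on simulated statistics called the 1 shifted list and 0 of 27 others. These statistics were drawn independently for each gene, so false calls from correlation between genes were not examined.

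Before the data were examined, 28 gene lists were fixed for steroid synthesis, signalling, inflammation, cell types and general processes, together with the tests and the rule for named genes. The planned list test was camera on log2 CPM per library. It needs named genes per library, so cameraPR of limma 3.58.1 was run on the authors' Wald score in its place, with a preset correlation of 0.01, without rows lacking a p and with Benjamini-Hochberg adjustment over the 28 lists. An estimated correlation cannot be had from one score per gene, and a preset of 0.05 was run instead. The p-values of the list test take genes as units at an assumed correlation, and do not measure the spread between samples. Where a symbol has 2 rows, the row with the higher mean entered the list.

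The rule names every measured cortisol synthesis gene, the 6 largest rises and 6 largest falls, and up to 2 genes past the threshold with the smallest p from each other list. For the largest changes it asks for a symbol, a mean of at least 1 and an adjusted p under 0.05. Its further condition, that the groups do not overlap, could be applied only to the count table, where it also gave the IDs named. Other genes named, such as IL6, IL1B, TNF, CYBB and all in the closing part, were chosen after their values were seen. Means of values per library are given with SD, fold changes with SE.

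Alternatives were RLE and upper-quartile factors, no filter and at least 10 counts in at least 5 libraries, DESeq2, limma-voom, and limma-trend on log2(TPM + 1) and log2(TPM + 0.1) with at least 0.5 TPM in at least 5 libraries, and without that filter. Sex as a covariate, each library left out in turn, and a block on the replicate numbers 2 to 5 completed them. Chance was examined by refitting on splits of the 10 libraries. There were 100, the real one included, with edgeR for each of group and sex and 100 with DESeq2 for group.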

Results

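Messenger RNA was measured by sequencing in 10 libraries of adrenal glands from sheep fetuses at 102 days of gestation. The labels put 5 libraries in an endotoxin group and 5 in a control group. The endotoxin group had been injected with endotoxin and the control group with saline. Endotoxin is lipopolysaccharide, a component of the outer membrane of Gram-negative bacteria that provokes inflammation. Each group held libraries of both sexes, with 3 labelled female and 2 male. The libraries held between 12494386 and 18324516 estimated counts, and an exact two-sided permutation test of depth between the groups gave p = 0.968. Pearson correlations of log2 CPM (counts scaled to a common library total) between libraries lay between 0.926 and 0.975, with a median of 0.961 within groups and 0.953 between groups, and no pair of libraries was counted as 1 sample.

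The first comparison asked how the adrenal transcriptome, and the genes of cortisol synthesis in particular, differed after exposure to endotoxin. Tested as sets, the lists of cortisol synthesis, cholesterol supply and neutrophil markers ranked higher in the endotoxin group, with 5 of 12, 2 of 19 and 7 of 13 measured genes rising singly. The cell cycle list ranked lower as a set, with 3 of 22 genes falling singly. CYP17A1, the 17-hydroxylase that directs steroids toward cortisol, had the largest change among the 12 measured genes of the cortisol list in the authors' deposited table, from a mean of 19.2 to 214 TPM (abundance scaled by transcript length and library total). The neutrophil calprotectin genes S100A8 and S100A9 went from 7.64 to 505 TPM and from 26.1 to 736 TPM in the authors' deposited table. TOP2A, a topoisomerase of dividing cells, fell from 8.79 to 4.96 TPM in the authors' deposited table. The authors' deposited table lists 330 rows with an adjusted p under 0.05, of which 248 were higher and 82 lower with endotoxin. That table holds no values per library, so its calls could not be examined by leaving libraries out. DESeq2 on the count table gave between 186 and 635 genes when 1 library was left out. The count table has other gene IDs, so this range is not that of the 330 rows.

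Named genes come from the authors' deposited table. The count table carries gene IDs of a form used for cattle, which the sources used here do not pair with symbols. The authors' deposited table calls its groups only A and B, and B was taken as endotoxin from the series title. Since that title itself says that cortisol-producing enzymes were high following inflammation, the direction of the cortisol list is not independent of that statement. The direction was checked apart from the title on changes of at least 8-fold, of which 16 were higher and 3 lower with endotoxin in the labelled TPM table, against 19 higher and 3 lower in B in the authors' deposited table.

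Among the 12 measured genes of the cortisol synthesis list, 5 rose, none fell and 7 did not pass. The list has 14 entries, of which CYP21A2 and CYP11B2 were not found in the authors' deposited table under the symbols listed. By adjustment over the list alone 8 rose, HSD11B2 among them, and none fell. STAR, which carries cholesterol into mitochondria, rose by a log2 fold change of 1.19 ± 0.29 (SE) in the authors' deposited table (adjusted p = 0.00817), from 481 to 1027 TPM. CYP11A1, the side-chain cleavage enzyme that makes pregnenolone, rose by 1.83 ± 0.35 (adjusted p = 8.56e-05) in the authors' deposited table. Its electron donor FDX1 rose by 1.75 ± 0.39 (adjusted p = 0.00181) in the authors' deposited table, to a mean of 1835 TPM. HSD3B1, which converts pregnenolone to progesterone, rose by 1.22 ± 0.30 (adjusted p = 0.00693), and CYP17A1 by 3.55 ± 0.72 (adjusted p = 0.000314), in the authors' deposited table. For CYP11B1, the 11-hydroxylase that completes cortisol, the authors' deposited table holds 2 rows, at 0.85 ± 0.38 (adjusted p = 0.295) and 0.83 ± 0.35 (adjusted p = 0.24). FDXR was at 0.74 ± 0.26 (adjusted p = 0.116) and HSD11B2, which inactivates cortisol, at 0.81 ± 0.29 (adjusted p = 0.126) in the authors' deposited table. POR at 0.19, TSPO at 0.20, HSD11B1 at 0.24 and CYB5A at -0.25 also missed the threshold in the authors' deposited table, with adjusted p between 0.845 and 0.952. As a set the list ranked above other genes by cameraPR on the authors' statistic, with a median log2 fold change of 0.83 and an adjusted p of 1.92e-09. On ranks of that statistic the cameraPR adjusted p was 0.000202. Such p-values of lists compare genes with genes and do not measure the spread between libraries.

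All 19 measured genes of the cholesterol uptake and synthesis list had a positive log2 fold change in the authors' deposited table, with a median of 1.32, and 2 passed singly. These were SCARB1, the receptor for high-density lipoprotein, at 1.61 ± 0.35 (adjusted p = 0.00111), and MVK, mevalonate kinase, at 1.48 ± 0.38 (adjusted p = 0.0121), in the authors' deposited table. With adjustment over the list alone, 15 rose and none fell. The list as a set passed by cameraPR (adjusted p = 1.46e-12).

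**Figure D1:**
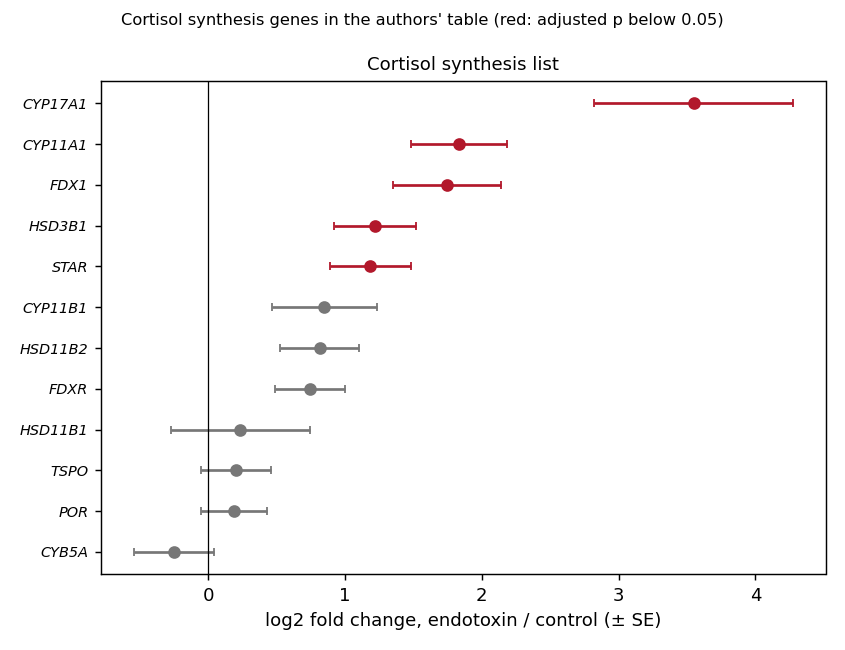
Model-based log2 fold change (endotoxin over control, horizontal axis) of the 12 measured genes of the cortisol synthesis list in the authors' deposited table. Points are the listed estimates, bars their standard errors, and red marks an adjusted p under 0.05, which 5 genes reach, with CYP17A1 farthest right at 3.55.

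The largest rises among genes with a symbol and a mean of at least 1 TPM included genes of neutrophil granules and antimicrobial peptides. CATHL3 rose by a log2 fold change of 6.57 ± 0.40, BAC5 by 6.01 ± 0.61 and MPO, myeloperoxidase, by 5.63 ± 0.54 in the authors' deposited table. S100A8 rose by 6.18 ± 0.42, S100A12 by 5.96 ± 0.42 and RETN by 5.47 ± 0.46 in the authors' deposited table, where the adjusted p of these 6 genes was at most 1.75e-19. MPO, at a control mean of 0.0679 TPM, was at 1.94 on the TPM scale, which adds 1 TPM to each mean and so understates changes of low genes. CATHL3 and BAC5 are cathelicidins, a family of related sequences, so the division of reads among its members is uncertain. Of the 13 measured neutrophil markers 7 rose, none fell and 6 did not pass, and 9 rose with adjustment over the list alone. S100A9 rose by 4.93 ± 0.33 (adjusted p = 1.65e-46) in the authors' deposited table. CYBB, a neutrophil oxidase gene, was at 0.08 ± 0.31 (adjusted p = 0.972) in the authors' deposited table. The set passed by cameraPR (adjusted p = 4.09e-56), with a median of 2.69. On ranks of the authors' statistic the cameraPR adjusted p was 1.19e-05.

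Lists of macrophage and red cell markers also passed. The macrophage and monocyte list passed (adjusted p = 1.73e-08), with 1 of its 14 measured genes past the threshold. That gene was MARCO, a scavenger receptor of macrophages, at 3.28 ± 0.45 (adjusted p = 3e-10) in the authors' deposited table, or 1.77 on the TPM scale. The erythroid list passed (adjusted p = 0.000189), with a median of 0.93, and 1 of its 6 measured genes rose. It was HBM, a globin gene, at 1.42 ± 0.34 (adjusted p = 0.00412) in the authors' deposited table, or 0.56 on the TPM scale. The lymphocyte list did not pass (adjusted p = 0.56), and none of its 15 measured genes did.

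In the lists of inflammatory genes few genes passed singly. In the list of acute inflammation and NF-kB targets 2 of 21 measured genes rose and none fell, and the set had an adjusted p of 0.0315. With a preset correlation between genes of 0.05 in place of 0.01 its adjusted p was 0.115. The 2 genes were CCL2, a monocyte chemoattractant, at 1.16 ± 0.34 (adjusted p = 0.0404), and TNFAIP3, an inhibitor of NF-kB signalling, at 1.17 ± 0.34 (adjusted p = 0.0407), in the authors' deposited table, where TNFAIP3 was at 0.65 on the TPM scale. The cytokine genes IL6, IL1B and TNF were listed at 0.12, -0.11 and -0.26, with adjusted p between 0.94 and 0.98, in the authors' deposited table. In the list of endotoxin recognition and acute phase genes 2 of 14 rose and none fell (set adjusted p = 0.000782). PTX3, a soluble pattern recognition protein, was at 2.19 ± 0.44 (adjusted p = 0.000162) and CD14, the endotoxin co-receptor, at 1.05 ± 0.24 (adjusted p = 0.00218) in the authors' deposited table. Of the 19 measured interferon response genes 3 rose, all of antigen processing, and the set did not pass (adjusted p = 0.0897). PSMB9 was at 1.14 ± 0.24 (adjusted p = 0.000654) and TAP1 at 0.81 ± 0.19 (adjusted p = 0.00369) in the authors' deposited table. The JAK-STAT3 list passed as a set (adjusted p = 0.0181) with none of its 11 genes past the threshold. It did not pass with a preset correlation of 0.05 (adjusted p = 0.0572) or on the TPM scale (adjusted p = 0.101).

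Of the 22 measured cell cycle genes 3 fell, none rose and 21 had a negative value, with a median of -0.41 and a set adjusted p of 1.32e-09. TOP2A was at -0.72 ± 0.18 (adjusted p = 0.00817) and BUB1B, a mitotic checkpoint kinase, at -0.65 ± 0.17 (adjusted p = 0.0124) in the authors' deposited table. With adjustment over the list alone 11 fell and none rose. NR3C1, the glucocorticoid receptor, was the single gene of its list to pass in the authors' deposited table, at -0.59 ± 0.17 (adjusted p = 0.044). The list of the receptor and its target genes did not pass as a set (adjusted p = 0.946). The largest falls among genes with a symbol and a mean of at least 1 TPM were in NEUROD4, a neuronal transcription factor (-1.80 ± 0.53), NRK (-1.63 ± 0.40) and RGS5, a pericyte gene (-1.51 ± 0.41), in the authors' deposited table. C16orf89 at -1.46, the adenylyl cyclase ADCY1 at -1.46 and the GABA receptor subunit GABRG1 at -1.34 followed, and the adjusted p of these 6 lay between 0.00726 and 0.0489 in the authors' deposited table. On the TPM scale NEUROD4 was at -0.995 and C16orf89 at -0.76.

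Of the 28 lists tested, 15 passed, 13 upward and 2 downward. Besides those above, the lists of unfolded protein response and chaperones (adjusted p = 0.000259), endothelial markers (0.000359), hypoxia and glycolysis (0.000359), oxidative phosphorylation (0.0181) and antioxidant defence (0.032) passed upward. The fibroblast and extracellular matrix list passed downward (adjusted p = 0.0306). With a preset correlation of 0.05 the adjusted p was 0.076 for oxidative phosphorylation, 0.102 for antioxidant and 0.101 for fibroblast genes, so these 3 calls were lost. On the TPM scale oxidative phosphorylation (adjusted p = 0.165) and antioxidant defence (0.101) did not pass either. Their medians were small, at 0.23, 0.33, 0.31, 0.17, 0.18 and -0.23. Single genes past the threshold in these lists were SDF2L1, an endoplasmic reticulum chaperone partner, at 1.06 ± 0.29, the glycolytic enzyme ENO1 at 0.57 ± 0.17 and the heme oxygenase HMOX1 at 1.17 ± 0.29, in the authors' deposited table. The lists of the ACTH receptor and cAMP signalling (adjusted p = 0.946), adrenal transcription factors (0.613), chromaffin cell markers (0.519), Schwann and glial markers (0.526) and zona glomerulosa and capsule markers (0.456) did not pass. Nor did those of ribosomal proteins (0.767), growth factors and fetal growth (0.326) and sex chromosome genes (0.972). The lists of adipose, liver and kidney markers (0.25) and immediate early genes (0.275) did not pass on the authors' statistic but passed downward on the TPM scale (adjusted p = 0.0157 and 0.000354).

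**Figure D2:**
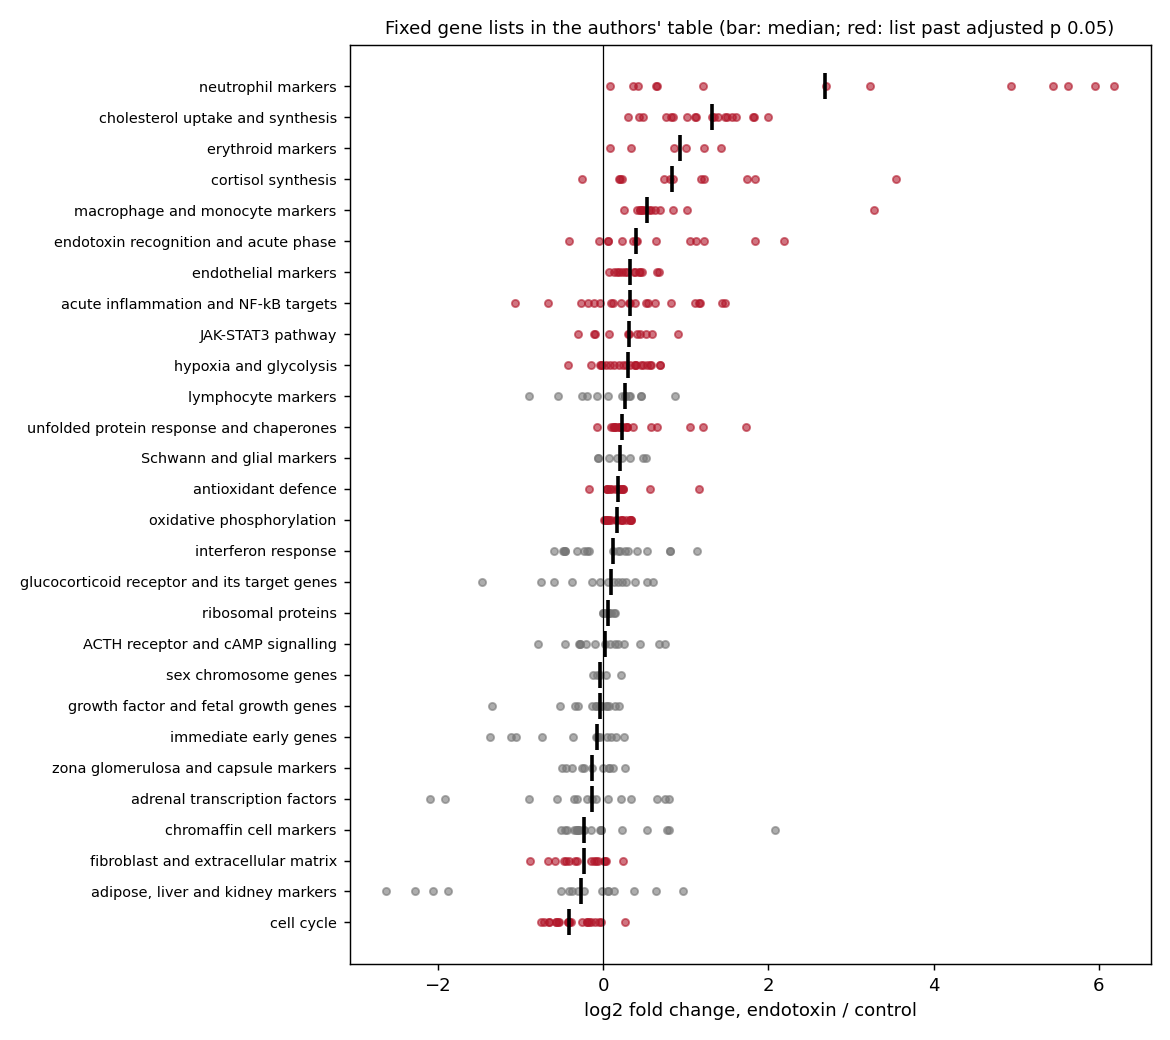
Model-based log2 fold change (endotoxin over control, horizontal axis) of each measured gene in the 28 fixed lists, from the authors' deposited table. Black bars are list medians and red marks lists with an adjusted p under 0.05; the neutrophil list has the highest median, 2.69, and the cell cycle list the lowest, -0.41.

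In the authors' deposited table of pathway enrichment, the category with the smallest p was valine, leucine and isoleucine biosynthesis, with 3 of its 4 annotated genes changed (BCAT2, SDSL and SDS, unadjusted p = 4.01e-05, adjusted p = 0.00381). A module of progesterone synthesis followed in the authors' deposited table, through CYP11A1 and HSD3B1 (2 of 2 genes, unadjusted p = 0.000474, adjusted p = 0.0225), and then a module of androgen synthesis through CYP17A1 and HSD3B1 (2 of 3 genes, unadjusted p = 0.00139, adjusted p = 0.0442). These 3 categories passed a Benjamini-Hochberg adjustment over the 95 distinct categories listed. Aldosterone synthesis and secretion, with 6 of 69 genes changed in the authors' deposited table (unadjusted p = 0.00379, adjusted p = 0.09), and NF-kappa B signalling, with 6 of 74 (unadjusted p = 0.00531, adjusted p = 0.101), did not. Each category in the authors' deposited table holds at least 2 changed genes, so the adjustment covers those listed and no others.

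The count table, which gives each library its own value, was tested without gene names. edgeR's quasi-likelihood test called 29 of 14869 genes at a Benjamini-Hochberg adjusted p under 0.05, of which 28 were higher with endotoxin. At an unadjusted p under 0.05 edgeR counted 2089 genes, a larger share of those tested than the 0.05 expected with no difference. In all 29 the values of the groups did not overlap, and 20 rose at least 8-fold. Over all tested genes 2.87% did not overlap, against 0.794% by chance. ENSBTAG00000012640.3 went from 0.848 ± 0.533 CPM (SD, n = 5) in controls to 60.8 ± 33.8 (SD, n = 5), a log2 fold change of 6.14 ± 0.48 (SE; edgeR adjusted p = 0.000112). ENSBTAG00000031599.2 went from 0.614 ± 0.226 to 38.4 ± 16.2 CPM (SD, n = 5), a change of 5.94 ± 0.38 (SE; edgeR adjusted p = 2.77e-05). The single gene that fell, ENSBTAG00000021162.5, went from 62.7 ± 3.28 to 35.6 ± 6.27 CPM (SD, n = 5), a change of -0.81 ± 0.13 (SE; edgeR adjusted p = 0.0231). DESeq2 called 368 genes from the same counts, 266 higher and 102 lower. Of these, 344 had an unadjusted edgeR p under 0.05. The DESeq2 count was 635 without endotoxin replicate 4, 201 without endotoxin replicate 2, 186 without control replicate 1 and 198 without control replicate 3. The edgeR count was 63 without endotoxin replicate 4, 17 without control replicate 1 and 18 without control replicate 3, and the fall of ENSBTAG00000021162.5 missed the threshold without endotoxin replicate 2 or 6 and without control replicate 1, 2, 3 or 5.

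On the first principal component of log2 CPM, with 24.5% of the variance, all endotoxin libraries lay below all control libraries. The means were -23.2 ± 18.5 (SD, n = 5) and 23.2 ± 14.1 (SD, n = 5), and an exact two-sided permutation test gave p = 0.00794, the smallest it can give. The second component, with 18.4%, did not separate the groups (exact permutation p = 0.556). In the TPM table control replicate 5 held 9 genes with at least 5 TPM and at least 20 times the highest value of any other library, together 1427 TPM, while each other library held at most 2. Without control replicate 5, edgeR called 22 genes and DESeq2 412.

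**Figure D3:**
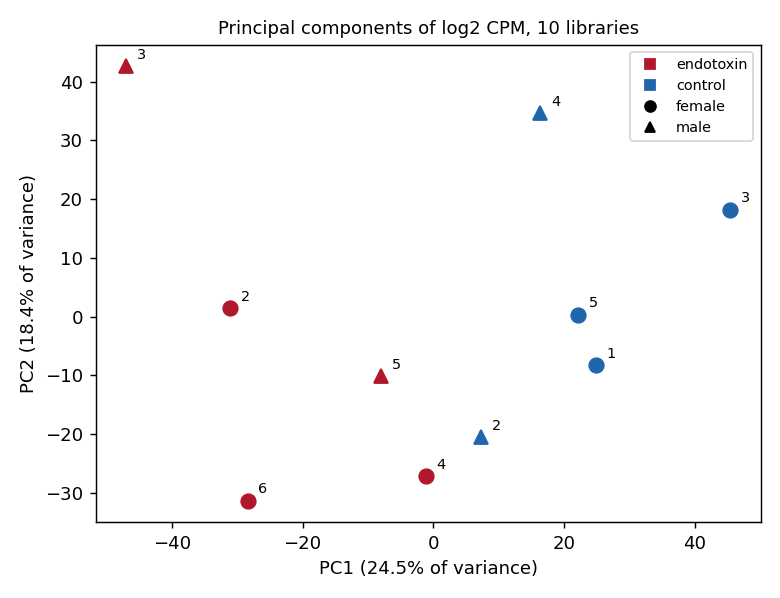
First and second principal components (arbitrary units) of log2 CPM for the 10 libraries, coloured by group, with circles for females and triangles for males and the replicate number beside each point. The endotoxin libraries lie between -47 and -1.2 on the first component and the control libraries between 7.25 and 45.4.

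The labels give a sex for each library, which allows a comparison of males and females. With group in the model, edgeR called none of 14869 genes as different between the 4 male and the 6 female libraries. At an unadjusted p under 0.05 edgeR counted 425 genes, a smaller share of those tested than the 0.05 expected with no difference. DESeq2 called none after adjustment. The 5 measured genes of the sex chromosome list belong to the comparison of endotoxin and control only, since the count table gives no symbols. For the same reason the sex labels were not checked on such genes. The absence of calls therefore does not show that the sexes were alike. For the difference of the endotoxin effect between sexes, edgeR's interaction test called none of 14869 genes, and DESeq2 called none. At an unadjusted p under 0.05 edgeR's interaction test counted 193, again a smaller share than 0.05. With edgeR, leaving out endotoxin replicate 6, a female, gave 4 genes, all with a lower effect in males. Leaving out endotoxin replicate 3, a male, gave 1, also lower in males, from a single remaining endotoxin male that is assumed to vary like the other libraries.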

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

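Both values here come from a comparison of each library with the other 4 of its group, in which chance marks about 1 in 20 groups. The 16 groups compared were 8 measures in each of the 2 groups. The tests of explanations below were chosen after the values were seen, except the one on the library that holds most outlying genes.

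Control replicate 5 held 9 genes expressed in it alone, where the other control libraries held 0 to 2. These genes summed to 1427 TPM, against 0 to 13 TPM in the other control libraries. Pancreatic enzyme genes are among the rows without a p in the authors' deposited table: the mean of CPA1, a carboxypeptidase, was 8.71 TPM in controls and 0.109 with endotoxin. CLPS, colipase, was at 17.9 and 1.87 TPM in the authors' deposited table. Pancreatic tissue in a control piece may be a source. Of 14 measured genes of an acinar list, 4 had a control mean at least 10 times the endotoxin mean, against 0.083% of all rows. Most of the list did not, and 6 of the 14 are among the rows without a p, where such genes were noticed. Of the 8 with a p none passed, with a median log2 fold change of -0.392, so pancreatic tissue as a source stays open. DESeq2 set aside 90 genes of the count table as single-library outliers, with 26.7% highest in control replicate 5 and 58.9% in endotoxin replicate 3. Whether the pancreatic genes belong to control replicate 5 could not be determined without names in the count table, and an effect of endotoxin on these genes was not tested.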

How the results depend on the processing

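The alternatives for gene lists, for the DESeq2 counts without single libraries and for the authors' deposited table were chosen after seeing the data. The edgeR count of 29 changed genes became 368 with DESeq2 (266 higher, 102 lower); every other scaling, filter, test or covariate gave between 22 and 31, and leaving out 1 library gave 17 to 63. Of the 29, all were among the DESeq2 calls in the same direction. The calls also differed in the simulation, which used edgeR's dispersions, with 42 false calls by DESeq2 and 1 by edgeR. Beyond that the cause was not tested. The replicate numbers 2 to 5 showed no pairing in the counts. Correlations of their deviations were 0.06, -0.06, -0.19 and 0.10, and none correlated best with its own number. Such values cannot show that the samples were unpaired. On those 8 libraries 12 genes were called with the replicate block and 16 without it, where fewer samples entered. DESeq2 called 186 to 635 genes without 1 library: 635 without endotoxin replicate 4, 201 without endotoxin replicate 2, 186 without control replicate 1 and 198 without control replicate 3. The sex count stayed at 0 in each alternative run, with 0 to 0 when 1 library was left out. The interaction count was 0 to 4 when 1 library was left out, and 0 with RLE factors, the stricter filter and DESeq2. The authors' deposited table gave 554 rows at an adjusted p under 0.1 in place of 330; the threshold itself is the cause. The number of lists passed, 15, was 10 to 15 in 4 alternatives, 10 with a correlation of 0.05. On the TPM scale 14 passed, 10 upward and 4 downward, of which 12 were among the 15. For lists, camera with an estimated correlation, fry, RLE factors, the stricter filter, the sex covariate, left-out libraries and the block were not run, since they need named genes per library. Both IDs that rose passed in all 22 alternatives; ENSBTAG00000021162.5 missed the threshold in 9 of 22, with an adjusted p of up to 0.287. Of 41 genes named from the authors' deposited table, 12 moved by more than their standard error on the TPM scale, MPO the most, from 5.63 to 1.94. None of these 41 turned its direction. CYBB, named outside the rule, did, from 0.08 to -0.071 on the TPM scale, and did not pass. At this depth and with 5 libraries per group, edgeR recovered 48% of simulated 2-fold changes in genes above a minimum mean count. Smaller changes were thus mostly not detectable.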

Other observations

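All tests of explanations in this part were chosen after the values were seen, except the splits with edgeR and DESeq2 for endotoxin against control.

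Single genes outside the fixed lists were also among those called. They were picked after their values were seen, and no theme is drawn from them. The serine dehydratases SDS and SDSL rose by a log2 fold change of 2.20 ± 0.41 and 2.82 ± 0.75 in the authors' deposited table (adjusted p = 3.92e-05 and 0.0173). The glutaminase GLS2 rose by 1.92 ± 0.30 and the branched-chain aminotransferase BCAT2 by 1.08 ± 0.23 in the authors' deposited table (adjusted p = 1.58e-07 and 0.000949). INHA, an inhibin subunit gene, rose by 1.28 ± 0.35 (adjusted p = 0.0226) in the authors' deposited table, while the related subunit gene INHBA was at -0.68 ± 0.37 and did not pass (adjusted p = 0.445). PNMT of the chromaffin list, which makes adrenaline, had means of 330 and 1307 TPM but did not pass (2.07 ± 0.73, adjusted p = 0.123) in the authors' deposited table. The mitotic genes NEK2 and HMMR fell, with NEK2 at -1.08 ± 0.20 and HMMR at -1.04 ± 0.22 in the authors' deposited table (adjusted p = 5.63e-05 and 0.000514).

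The rise of neutrophil markers was set against more blood of unchanged composition in the endotoxin glands, which would raise red cell markers alike. The erythroid list had a median log2 fold change of 0.932 with an SD of 0.517 over its 6 measured members. That lay below the neutrophil median of 2.69 by more than the erythroid SD. The SD of the neutrophil list, 2.45, was however wider than the gap between the medians, so the part of blood volume was not decided. More neutrophils or their precursors, in the gland or its blood, may contribute. A further neutrophil list, which shares 1 gene with the fixed lists, had 16 measured genes, all 16 positive, with a median of 1.37. Of these 7 passed, and 10 rose with adjustment over the list alone. A larger number of such cells stays open, since under 50% of these genes passed over all genes and CYBB did not. A change of expression within resident cells was not tested.

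The rise of cortisol synthesis genes could in part reflect a larger share of cortex in the endotoxin pieces. Of 20 other cortex genes listed, 9 are also in a fixed list, and 16 were measured, of which 3 rose and 13 did not pass; 10 rose with adjustment over the list alone, and 5 had a negative value. Without FDXR, which the cortisol list holds, the median of the remaining 15 was 0.567, beside 0.831 for the cortisol list, and their SD of 1.45 was wider than the change to be explained, so the test does not decide. The criterion first written for this explanation was met, but with so wide a spread it could hardly have failed, and it was set aside after the result was seen. The chromaffin list had a median of -0.23, and an effect of endotoxin on the cortisol genes, the contrast of the design, also stays open.

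With edgeR, 1 of 100 splits of the 10 libraries, the real one, gave as many as 29 genes. The highest other split gave 3, so a random split is an unlikely source of that count. Chance is not excluded, since the other splits mix the groups, which can widen their spread and lower their counts. The labels also do not state that each library is from a separate fetus. With DESeq2, 5 of 100 splits gave at least the 368 genes of the real one, and the highest other gave 642, so chance cannot be excluded for that count. The highest split set endotoxin replicates 2, 3, 4 and 5 with control replicate 5 against the rest. Such a split keeps most endotoxin libraries together, so its count can hold part of the endotoxin contrast. A split with 436 genes also held 4 endotoxin libraries on one side. Those with 441 and 408 genes held 3 and 2 endotoxin libraries beside endotoxin-free places filled by controls. A smaller draw of splits made first with DESeq2 gave the same reading. For sex the real count was 0, which 100 of 100 splits reach whatever the data, so the splits say nothing about chance there; the highest other gave 3. The authors' deposited table could not be examined this way, so chance was not tested for its 330 rows or for single genes taken from it.

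Neuronal genes were also among the rows without a p in the authors' deposited table, such as SNCG with means of 249 and 456 TPM and NPY with 394 and 544. Of 23 measured peripheral neuron genes 5 lacked a p, against 0.41% of all rows, and 3 of the 24 genes listed are also in a fixed list. A candidate source is nerve or ganglion tissue in one or more endotoxin pieces, for which genes without a p and with an endotoxin mean at least 2 times the control mean were counted. The count was 0 of 23, but SNCG and NPY, which prompted it, lie under that limit themselves, so it decides nothing and the source stays open. GUCA2A, which encodes guanylin, had means of 1.76 and 24.2 TPM and no p in the authors' deposited table.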
